A study of Mus musculus with 6 samples.

How the data were processed

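Gene expression was measured on 6 single-channel Affymetrix whole-transcript arrays, 3 of mouse primary hepatocytes infected with a GFP-expressing strain of Plasmodium yoelii, a rodent malaria parasite, and 3 of hepatocytes from a culture without infection. Per the labels' protocols, cells were detached with trypsin, sorted by flow cytometry, and total RNA was extracted and converted to biotin-labelled cDNA. Infected cells were collected 36 hours after infection and were gated on parasite fluorescence. No hours are recorded for the uninfected cells, so an equal time in culture cannot be assumed. The treatment field of the labels mentions sporozoites for all 6 samples. The groups used here follow the sample titles and the infection field, which separate infected from uninfected.

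The deposited values are log2 probe set signals, 1 column per array, summarised by the authors with Affymetrix Expression Console per the submitters' processing notes. The software version, the summarisation and normalization method, the annotation release and the genome build are not given in the sources used here, and no coordinates are reported. The main table, a workbook sheet of 80202 probe sets, ranges from 0.84 to 14.2, which fits a log2 scale and not read counts. A second deposited table of log2 values, with 72688 probe sets, shares 65956 of them. Its values differ from the first by a median of 0.0246, and it served as an alternative.

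Of the probe sets in the main table, 40161 carry 1 gene symbol and 40041 carry none. Symbols were used as the table gives them. For each of 39492 genes, the probe set with the highest mean over the 6 arrays was kept, and 468 genes had more than 1 probe set. Of these genes 32418 matched a symbol or synonym in RefSeq for mouse assembly GRCm38.p6, which was used only for gene class and chromosome, and 7074 did not. On this array 841 genes share exactly the values of another gene and cannot be told apart from it, and keeping 1 gene per set would remove 602. No further normalization and no filter on dim probe sets was applied.

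Infected and uninfected arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, on all 6 arrays. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are infected minus uninfected on the log2 scale, given with the moderated standard error. Where a gene's mean lay below the median of the 10553 negative-control probe sets in 1 group, the fold is a bound against that median and is written "at least". With 3 arrays against 3, a two-sided exact permutation test cannot give a p below 0.1, so array-wide measures cannot reach the threshold. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

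Before the data were examined, 42 gene lists were fixed, with 903 genes of which 894 were measured. They cover interferon and inflammatory responses, lipid and energy metabolism, hepatocyte functions, stress responses, growth, host factors of malaria liver stages, other liver and blood cell types, and sex-linked genes. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists. A camera test with the correlation estimated from the data, and fry, which asks only whether a list's genes move on balance one way, were alternatives. The rule for genes named in the text was also fixed then. It takes the 12 largest rises and 12 largest falls among genes that pass with no overlap between groups, leaving out predicted genes, small RNAs and olfactory and vomeronasal receptors. It adds up to 4 members of each list by smallest p, every listed host factor and every listed sex-linked gene. Genes named outside this rule are marked as chosen after their values were seen. A few genes that the rule names are not reported here.

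The other alternatives were quantile normalization, subtraction of array medians or of 75th percentiles, removal of dim genes below the 25th or 50th percentile, the mean of all probe sets per gene, every probe set tested separately, eBayes with trend and robust options, array weights, the second deposited table, the replicate number as a block, lists without shared genes, and each array left out in turn. A planned change of pseudocount was not run, since the values are already logarithms. Added after seeing the data were fits on protein-coding genes, on 1 gene per set of identical values, and without sex-linked and sex-biased genes. The procedure was tested on simulated data for the comparison of infected with uninfected arrays, over 39492 genes. It recovered 87.0% of genes changed by 1 log2 unit and 46.0% of those changed by 0.5, with 2.61% unchanged genes among its calls. The simulated data held far fewer changed genes than were called in the real data, and noise that was independent between genes. These shares may therefore differ in the real data, and the check says nothing of list calls among correlated genes.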

Results

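Transcript levels in primary mouse hepatocytes carrying liver-stage P. yoelii were compared with those in hepatocytes of an uninfected culture, to ask how infection by the parasite is accompanied by changes in the host cell. There were 3 arrays per group. Median log2 signal over all genes was 4.34 ± 0.02 (SD, n = 3) on infected and 4.28 ± 0.03 (SD, n = 3) on uninfected arrays. Arrays correlated at 0.994 to 0.996 within the infected group, at 0.997 to 0.998 within the uninfected group and at 0.980 to 0.983 between groups, across genes, which are not independent replicates. The first principal component held 76.2% of the variance and separated the groups. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these arrays, which may be technical.

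Infected hepatocytes had higher levels of inflammatory and interferon-induced transcripts and lower levels of cholesterol synthesis, lipid metabolism and cytoskeletal transcripts. With an estimated correlation between genes the list of cholesterol synthesis alone passed (adjusted p = 0.048), and the lists behind the other changes had adjusted p = 0.133 to 0.394. The acute-phase gene Saa3 rose 10.9-fold, from 7.47 ± 0.14 to 10.91 ± 0.06 (log2, SD, n = 3). Cxcl2, which encodes a neutrophil chemokine, rose 6.11-fold. Vim, encoding the intermediate filament protein vimentin, fell by 3.44 on the log2 scale, and Cyp4a14, a fatty acid omega-hydroxylase gene, fell from 8.34 ± 0.06 to 3.66 ± 0.15 (log2, SD, n = 3), below the median of the negative controls. In all, 9155 of 39492 genes changed, 4435 higher and 4720 lower (limma, adjusted p under the threshold of 0.05). At least 2-fold changes were found for 1049 genes, 747 higher and 302 lower. Among the 20711 protein-coding genes, 1722 rose and 3247 fell, and 357 changed at least 2-fold, 119 higher and 238 lower. The groups did not overlap for 41.3% of genes, where chance gives 10%. Without uninfected replicate 1 or 3 the count of changed genes was 6057 or 5989, and with array medians subtracted the split was 3007 higher and 5835 lower. On the same arrays as all gene groups described here, Y-linked transcripts (Ddx3y at least 8.15-fold) and hybridisation controls (0.95 on the log2 scale) were higher in the infected group.

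Among the remaining large rises, Vnn3, a vanin family gene, rose by 2.50 ± 0.07 (log2 difference ± SE, adjusted p = 6.1e-07), Slc7a2, a cationic amino acid transporter gene, by 2.16 ± 0.08, and Cdo1, which encodes cysteine dioxygenase, by 2.11 ± 0.06. Tgtp2, an interferon-induced GTPase gene, rose by 2.19 ± 0.11. Cybb, the gene of the phagocyte NADPH oxidase subunit gp91phox, was at least 5.01-fold higher, C6, encoding a complement component, at least 4.20-fold higher, and Cyp4a12a at least 2.93-fold higher. Large falls included Sytl5 (-3.31 ± 0.09), Dpysl2 (-2.60 ± 0.07), the growth factor gene Igf1 (-2.59 ± 0.08), the urea cycle gene Otc (-2.76 ± 0.10) and the sulfotransferase gene Sult1e1 (-2.91 ± 0.08), while Sult2a2 was at least 7.32-fold lower. Cyp3a41a and Cyp3a41b fell by 3.16 and 3.13; the genes are near-identical copies whose probes may not separate them. In mouse liver C6 and Cyp4a12a are male-biased, and Cyp4a14, Sult1e1, Sult2a2, Cyp3a41a and Cyp3a41b are female-biased, by a list compiled after the results were seen.

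**Figure D1:**
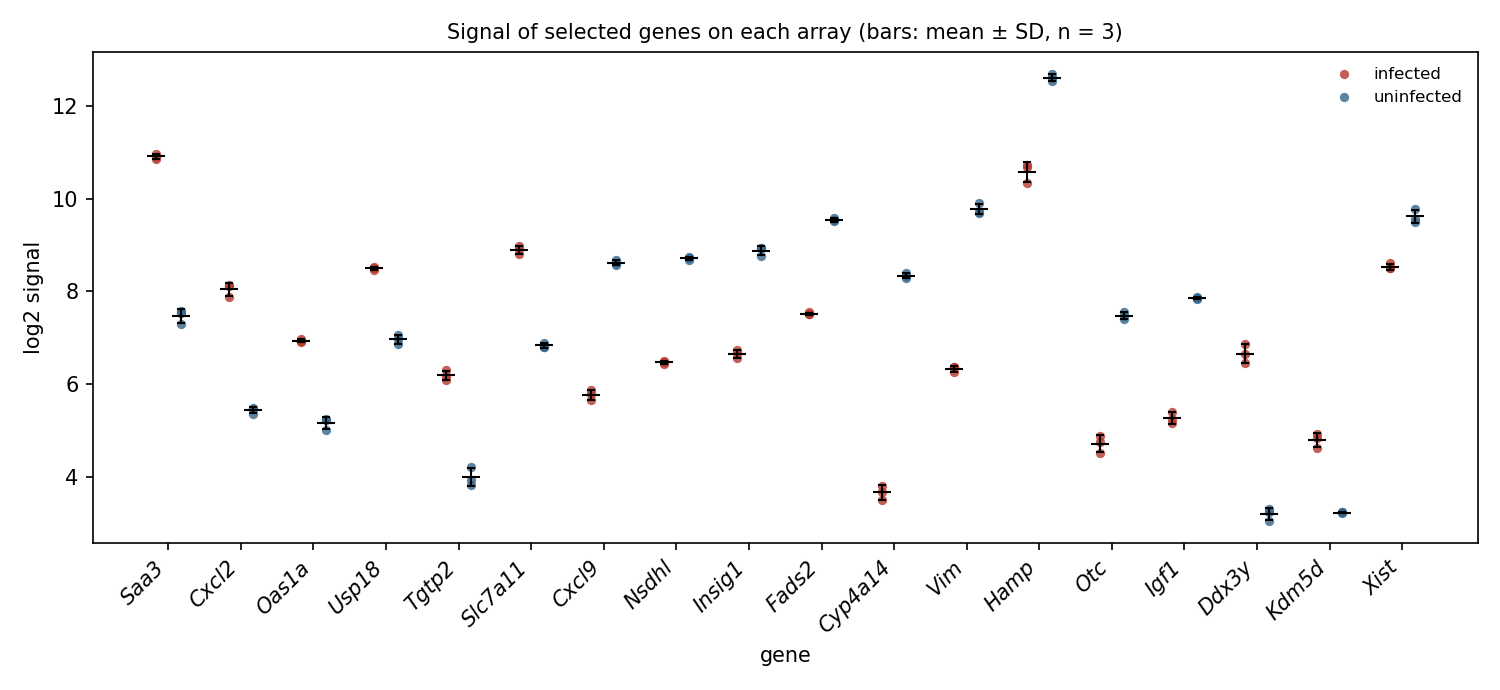
Log2 signal (vertical axis) of selected genes (horizontal axis) on each of the 6 arrays, infected in red and uninfected in blue, with black bars for mean ± SD (n = 3). The groups do not overlap for any gene shown, and Ddx3y lies at 6.66 on infected and 3.20 on uninfected arrays.

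Interferon-stimulated genes rose together. Of 37 measured, 28 rose, 0 fell and 9 did not pass, with a median log2 difference of 0.47. Adjusted over the list alone, 33 rose. Oas1a, which encodes an enzyme that senses double-stranded RNA, rose by 1.79 ± 0.08, Usp18, a feedback inhibitor of interferon signalling, by 1.53 ± 0.07, Zbp1 by 1.22 ± 0.06 and Oasl2 by 1.21 ± 0.08. The list passed the camera test (adjusted p = 7.2e-14), with adjusted p = 0.133 with an estimated correlation. Among 18 interferon-gamma-type GTPases and targets, 8 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone. Gbp4 rose by 1.12 ± 0.10, Iigp1 by 0.93 ± 0.06 and Gbp3 by 0.81 ± 0.07, GTPases that act on vacuoles of intracellular pathogens. The chemokine gene Cxcl9, in the same list, fell by 2.85. The median was 0.25 (adjusted p = 0.0033; adjusted p = 0.333 with an estimated correlation). For MHC class I antigen presentation, 12 of 18 genes rose and 3 fell, and 13 rose and 3 fell adjusted over the list alone. Immunoproteasome genes Psmb8 and Psmb9 rose by 1.02 ± 0.07 and 0.54 ± 0.06, the peptide transporter gene Tap1 by 0.87 ± 0.07 and H2-Q7 by 0.75 ± 0.07 (list median 0.39, adjusted p = 9.6e-04; adjusted p = 0.343 with an estimated correlation). Of 24 genes for innate sensing and interferon receptors 5 rose and 2 fell, and 5 and 3 when adjusted over the list alone. Tlr2 rose by 0.93 and Ifnar1 fell by 0.32, and the list did not pass (adjusted p = 0.435) except with fry.

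NF-kB targets, cytokines and chemokines were also higher. Of 27 genes 17 rose and 1 fell, and 23 rose and 1 fell adjusted over the list alone. Besides Cxcl2, Cxcl5 rose by 1.97 ± 0.10, the NF-kB inhibitor gene Tnfaip3 by 1.58 ± 0.07 and the monocyte chemokine gene Ccl2 by 1.13 ± 0.06 (list median 0.36, adjusted p = 3.2e-08; adjusted p = 0.133 with an estimated correlation). Of 26 acute-phase genes 18 rose and 4 fell, and 20 and 4 adjusted over the list alone. Orm2 rose by 1.67 ± 0.07, Cebpd by 1.66 ± 0.08 and Steap4 by 1.28 ± 0.06, while Hamp, encoding the iron hormone hepcidin, fell by 2.03 (list median 0.32, adjusted p = 1.1e-05; adjusted p = 0.394 with an estimated correlation). Complement and coagulation genes went both ways, with 10 of 30 higher and 10 lower (10 and 12 adjusted over the list alone). C6 rose, Serpinc1, the antithrombin gene, fell by 1.21 ± 0.06, C8g by 1.28 ± 0.08 and Masp1 by 1.20 ± 0.07. That list did not pass (adjusted p = 0.663), and its median of -0.0036 and mean of 0.03 differ in sign.

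Cholesterol synthesis showed the most uniform fall of any list tested. All 24 measured genes of cholesterol synthesis and SREBP2 targets fell, over all genes and adjusted over the list alone, with a median of -1.18. Nsdhl (-2.25 ± 0.06), Fdps (-1.92 ± 0.07) and Hsd17b7 (-1.75 ± 0.06) encode enzymes of the pathway, and Insig1 (-2.23 ± 0.08) a sterol-regulated inhibitor of it. It was the 1 list of 42 to pass both with the preset correlation (adjusted p = 3.0e-26) and with an estimated one (adjusted p = 0.048). Of 21 genes of fatty acid and triglyceride synthesis 14 fell and 1 rose, the same counts adjusted over the list alone. The desaturase genes Fads2, Scd1 and Scd2 fell by 2.02, 1.80 and 1.76, and Dgat2, which encodes an enzyme of triglyceride assembly, rose by 1.92 (list median -0.35, adjusted p = 3.3e-08; adjusted p = 0.208 with an estimated correlation). Of 24 genes of fatty acid oxidation and PPAR-alpha targets 15 fell and 3 rose, and 15 and 4 adjusted over the list alone. Besides Cyp4a14, Cyp4a10 fell by 3.57 ± 0.11, Cidec, encoding a lipid droplet protein, by 1.92 ± 0.10 and the kinase gene Pdk4 by 1.72 ± 0.08 (list median -0.33, adjusted p = 9.1e-07; adjusted p = 0.394 with an estimated correlation). Y-linked transcripts, described with the sex-linked genes, moved with these falls on all 6 arrays.

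**Figure D2:**
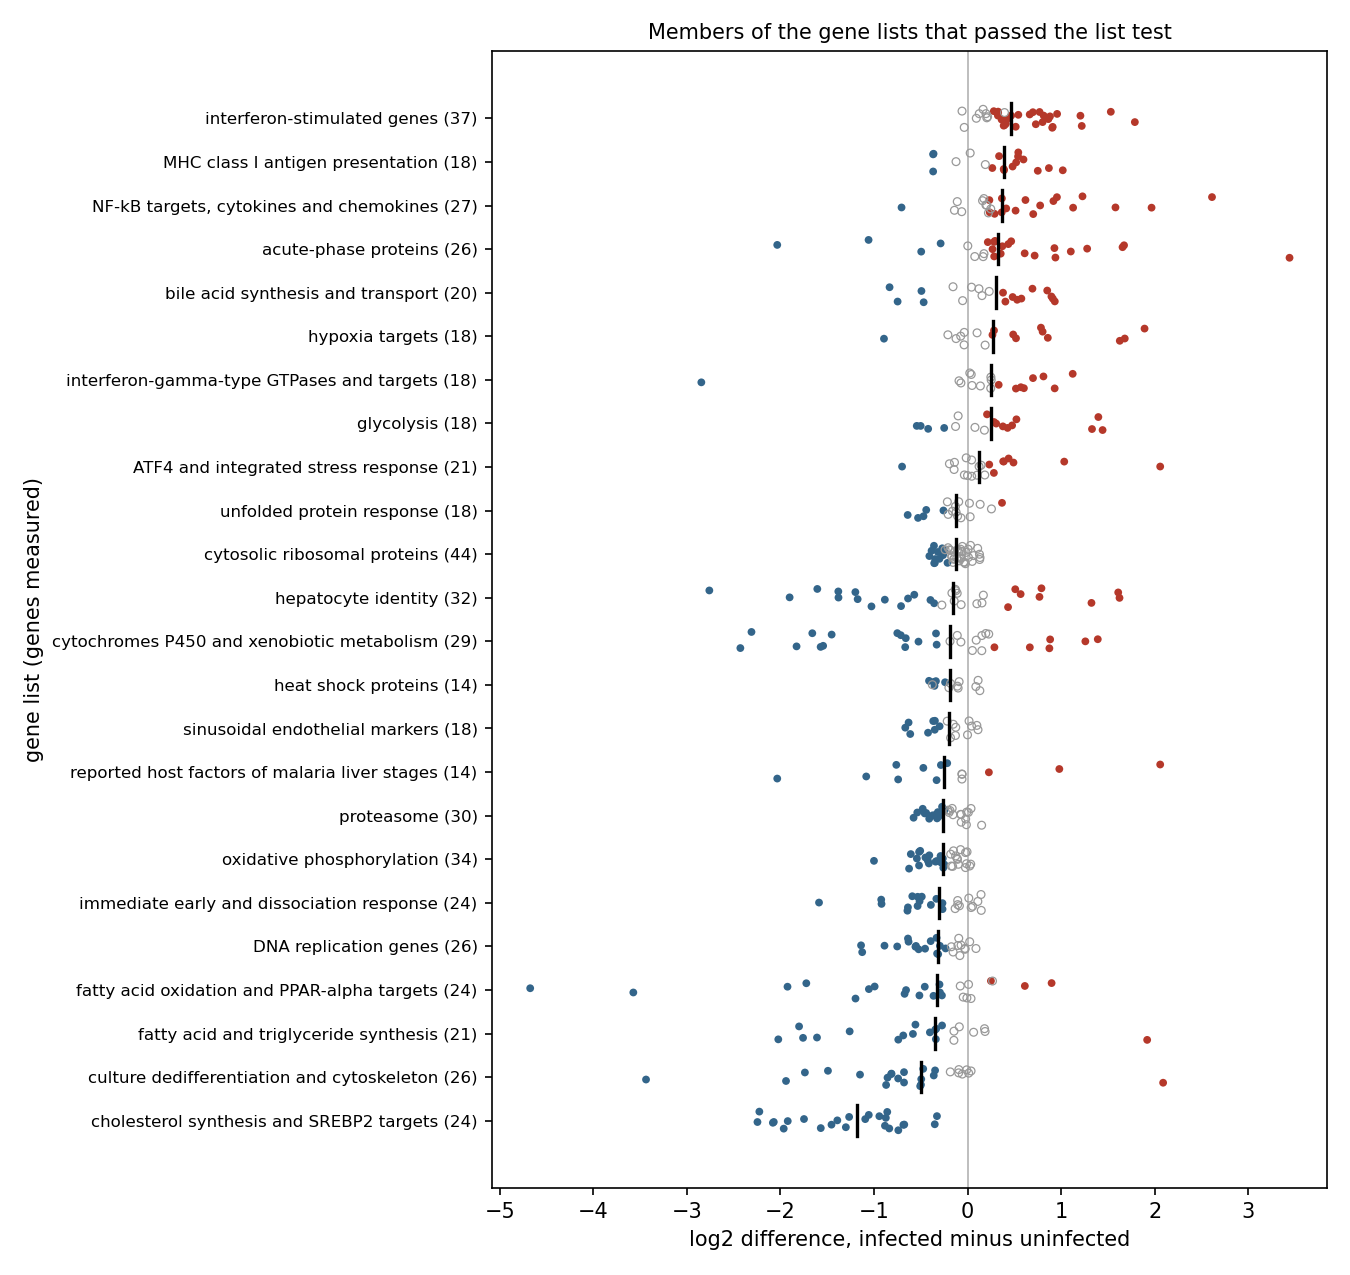
Log2 difference, infected minus uninfected (horizontal axis), of each measured gene in the 24 lists other than sex-linked genes that passed the list test (vertical axis, with the number measured); red and blue points rose or fell, open points did not pass, and black bars are list medians. All 24 points of the cholesterol synthesis list lie below 0, around a median of -1.18.

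Hepatocyte genes went in both directions. Of 32 hepatocyte identity genes 14 fell and 8 rose, and 16 and 9 adjusted over the list alone. Besides Otc, the apolipoprotein genes Apoa2, Apoa1 and Apoh fell by 1.90, 1.61 and 1.38 (list median -0.16, adjusted p = 0.0029; adjusted p = 0.394 with an estimated correlation). Of 29 cytochromes P450 and genes of xenobiotic metabolism 14 fell and 6 rose, and 15 and 8 adjusted over the list alone. Cyp2b9, female-biased by the list compiled afterwards, fell by 2.43 ± 0.07, Cyp2c37 by 2.31 ± 0.06 and Cyp2c50 by 1.83 ± 0.07 (list median -0.19, adjusted p = 0.0029; adjusted p = 0.452 with an estimated correlation). The calls of both lists were also lost with quantile normalization and among genes above the median signal. Y-linked transcripts moved with these genes too. Of 13 pericentral genes 5 fell and 2 rose, with the same counts adjusted over the list alone. Cyp1a2 and Cyp2e1 fell by 1.66 and 1.57, Lect2 fell by 0.96, and the glutamate transporter gene Slc1a2 rose by 0.97. The list did not pass (adjusted p = 0.150) except with fry, and its median of 0.04 and mean of -0.28 differ in sign. Of 14 periportal genes 5 rose and 2 fell, and 6 and 2 adjusted over the list alone (median 0.19, adjusted p = 0.112). The periportal list passed with fry, with quantile normalization, among genes above the median signal and among protein-coding genes, the last a choice made after seeing the data. Pck1, a gluconeogenesis gene, rose by 1.15 and the urea cycle genes Cps1 and Ass1 fell by 1.01 and 0.69. Of 20 genes of bile acid synthesis and transport 10 rose and 4 fell, the same adjusted over the list alone, with Baat at 0.90 ± 0.06 and Slc27a5 at -0.83 ± 0.07 (list median 0.30, adjusted p = 0.041; adjusted p = 0.394 with an estimated correlation). That call was also lost without sex-linked and sex-biased genes, a set chosen after seeing the data, without infected or uninfected replicate 1, with 75th percentiles subtracted and among genes above the median signal.

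Glycolytic and hypoxia-responsive genes were higher. Of 18 glycolysis genes 10 rose and 4 fell, and 11 and 4 adjusted over the list alone. Pkm rose by 1.44 ± 0.07, Pfkp by 1.40 ± 0.06 and Pfkfb3 by 1.33 ± 0.06 (list median 0.24, adjusted p = 0.041; adjusted p = 0.394 with an estimated correlation). Of 18 hypoxia targets 10 rose and 1 fell, and 11 and 2 adjusted over the list alone. Adm, encoding adrenomedullin, rose by 1.89 ± 0.09, the oxygen sensor gene Egln3 by 1.68 ± 0.06 (0.95 as the mean of all its probe sets) and Bnip3 by 1.63 ± 0.08, and Bhlhe40 fell by 0.89 (list median 0.27, adjusted p = 0.0021; adjusted p = 0.333 with an estimated correlation). Genes of oxidative phosphorylation were lower, with 19 of 34 fallen and 0 risen (21 and 0 adjusted over the list alone). Uqcrb fell by 0.63 and Uqcrc1 by 0.61, both genes of respiratory complex III (list median -0.26, adjusted p = 6.2e-09; adjusted p = 0.333 with an estimated correlation). The glycolysis call was also lost without infected replicate 1 or 2 or uninfected replicate 1, with 75th percentiles subtracted and without genes shared between lists.

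Some lists of stress pathways passed and others did not, and the lists were not tested against each other. Of 21 ATF4 and integrated stress response genes 8 rose and 1 fell, the same adjusted over the list alone. The cystine transporter gene Slc7a11 rose by 2.06 ± 0.07 and the asparagine synthetase gene Asns by 1.03 ± 0.07, while Slc3a2, encoding the partner subunit of that transporter, fell by 0.70 ± 0.06 (list median 0.12, adjusted p = 0.041; adjusted p = 0.394 with an estimated correlation). The call was also lost without infected replicate 1, uninfected replicate 1 or uninfected replicate 3, with array medians subtracted and without genes shared between lists. Of 18 genes of the unfolded protein response 5 fell and 1 rose, and 7 and 2 adjusted over the list alone, with Dnajc3 at -0.64 ± 0.08 (list median -0.13, adjusted p = 0.0085; adjusted p = 0.366 with an estimated correlation). Of 14 heat shock genes 5 fell and 0 rose, and 8 fell adjusted over the list alone, with Hspa8 at -0.41 ± 0.06, or -0.22 with quantile normalization (list median -0.19, adjusted p = 0.0056; adjusted p = 0.394 with an estimated correlation). Both of these calls were also lost with quantile normalization and among genes above the median signal, and that of the unfolded protein response among genes above the 25th percentile of signal. Among 19 NRF2 targets 6 rose and 5 fell, and 6 and 7 adjusted over the list alone. G6pdx rose by 1.34, and Tkt and Me1 fell by 0.72 and 0.74. The list did not pass (adjusted p = 0.438), and its median of -0.16 and mean of 0.08 differ in sign. Of 22 p53 targets 3 rose and 8 fell, and 4 and 9 adjusted over the list alone. Fas rose by 0.98, and Perp and Cdkn1a fell by 1.05 and 0.94 (median -0.03, adjusted p = 0.070), and the list passed with fry and without uninfected replicate 1. Of 23 apoptosis regulators 5 rose and 6 fell, the same adjusted over the list alone. Birc2, encoding an inhibitor of apoptosis, rose by 1.57 (0.95 as the mean of all its probe sets), and Casp8 and Bcl2l1 fell by 0.80 and 0.60. The list did not pass (adjusted p = 0.555), and its median of -0.04 and mean of 0.02 differ in sign.

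Genes of DNA replication fell, and no mitotic gene passed. Of 26 replication genes 16 fell and 0 rose, and 18 fell adjusted over the list alone. The helicase genes Mcm3 and Mcm4 fell by 1.14 and 1.13 and Pcna by 0.89 (list median -0.32, adjusted p = 4.0e-09; adjusted p = 0.060 with an estimated correlation). None of 24 mitotic genes passed, which is 0 risen and 0 fallen, also adjusted over the list alone (median 0.01, mean -0.0036, adjusted p = 0.663). Of these 24 genes 11 had a mean signal below the negative-control median, against 2 of the 26 replication genes. The lack of mitotic calls may thus reflect signal near background and does not show unchanged expression. Among 30 proteasome genes 16 fell and 0 rose, and 19 fell adjusted over the list alone, with Psmd12 at -0.58 ± 0.06 (list median -0.26, adjusted p = 2.4e-07; adjusted p = 0.394 with an estimated correlation). Of 44 cytosolic ribosomal protein genes 12 fell and 0 rose, and 13 fell adjusted over the list alone, with Rpl18 at -0.36 ± 0.06 (list median -0.13, adjusted p = 9.2e-05; adjusted p = 0.444 with an estimated correlation). The ribosomal call was also lost with quantile normalization and among genes above the median signal, and the list median lay between -0.19 and -0.02 over the alternatives. Of 21 autophagy genes 5 rose and 3 fell, and 6 and 4 adjusted over the list alone, with Atg14 and Nbr1 both at 0.58 and Gabarapl2 at -0.33 (median 0.10, adjusted p = 0.663), a list that passed only with quantile normalization. Of 24 lysosome genes 2 rose and 8 fell, and 3 and 8 adjusted over the list alone, with Cd63 at -0.45 ± 0.07 (median -0.05, adjusted p = 0.144).

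Genes listed for dedifferentiation in culture and the cytoskeleton were lower on infected arrays. Time in culture could not be compared between the groups, so these changes cannot be assigned to infection. Of 26 dedifferentiation and cytoskeleton genes 18 fell and 1 rose, the same adjusted over the list alone. Besides Vim, Ctgf fell by 1.94 ± 0.08 and Lgals1 by 1.49 ± 0.07 (list median -0.50, adjusted p = 9.6e-12; adjusted p = 0.133 with an estimated correlation). On the same arrays some markers of other cell types were lower, with 8 of 18 sinusoidal endothelial markers fallen (list adjusted p = 4.1e-04; adjusted p = 0.133 with an estimated correlation) and 4 of 15 cholangiocyte markers, among them Spp1, Cldn4 and Pkhd1 at -1.85, -1.64 and -1.36. Another 2 cholangiocyte markers rose, among them Bicc1 at 0.79, and that list did not pass (median 0.04, adjusted p = 0.251) except with fry. Of 24 immediate early and dissociation response genes 14 fell and 0 rose, the same adjusted over the list alone. Dusp1 fell by 1.59 ± 0.09, Myc by 0.92 ± 0.08 and Fos by 0.59 ± 0.07 (list median -0.30, adjusted p = 3.6e-06; adjusted p = 0.133 with an estimated correlation).

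Of 14 reported host factors of malaria liver stages 8 fell and 3 rose, the same adjusted over the list alone. Hamp fell by 2.03 ± 0.11, Trp53 by 1.08 ± 0.12, the ephrin receptor gene Epha2 by 0.76 ± 0.07 and the fatty acid binding protein gene Fabp1 by 0.74 ± 0.11. The tetraspanin genes Cd81 and Cd9 fell by 0.47 (0.28 with quantile normalization for Cd81) and 0.29, the scavenger receptor gene Scarb1 by 0.33 and Met, the hepatocyte growth factor receptor gene, by 0.22. Slc7a11 rose by 2.06 ± 0.07, the heme oxygenase gene Hmox1 by 0.98 ± 0.10 and Map1lc3b by 0.23 ± 0.07 (adjusted p = 0.050, just under the threshold). Aqp3, Gpx4 and Bcl2 did not pass, each at -0.06. The list passed (median -0.25, adjusted p = 0.010; adjusted p = 0.394 with an estimated correlation), and its call was also lost with quantile normalization and with either filter on dim genes. The calls of Met and Map1lc3b were lost on leaving out any 1 of the 6 arrays, and that of Cd9 without infected replicate 2 or uninfected replicate 1 or 2 and with quantile normalization. The call of Met was also lost with quantile normalization, 75th percentiles subtracted and the second deposited table, and that of Map1lc3b with array medians subtracted. Of 21 genes of iron and heme handling 5 rose and 8 fell, and 5 and 10 adjusted over the list alone. Hamp2 and Id1 fell by 1.95 and 1.45, and the metal transporter gene Slc39a14 rose by 0.74 (median -0.13, adjusted p = 0.094), and the list passed with fry alone.

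Of the marker lists of other cell types, that of sinusoidal endothelium passed camera. With fry, which does not compare a list with other genes, those of cholangiocytes, neutrophils and Kupffer cells passed as well. Sinusoidal endothelial markers were lower, with 8 of 18 fallen and 0 risen, the same adjusted over the list alone. Eng, Cdh5 and Fcgr2b fell by 0.67, 0.63 and 0.61 (list median -0.20, adjusted p = 4.1e-04; adjusted p = 0.133 with an estimated correlation). Of 18 Kupffer cell and macrophage markers 3 rose and 3 fell, and 4 and 3 adjusted over the list alone. Mpeg1, encoding the macrophage pore protein perforin-2, rose by 1.76 ± 0.11 and Cd14 fell by 0.32 ± 0.08 (list median 0.03, adjusted p = 0.817). The call of Cd14 was lost on leaving out any 1 array except infected replicate 1. Of 17 stellate cell and fibroblast markers 1 rose, Dcn, whose means lay below the median of the negative controls in both groups, and 0 fell, the same adjusted over the list alone (median -0.01, mean 0.02, adjusted p = 0.723). Of 15 cholangiocyte markers 2 rose and 4 fell, the same adjusted over the list alone. Spp1, Cldn4 and Pkhd1 fell by 1.85, 1.64 and 1.36, Bicc1 rose by 0.79 ± 0.09, and the list did not pass (median 0.04, mean -0.25, adjusted p = 0.251). No lymphocyte and NK cell marker of 19 passed (0 risen and 0 fallen, also adjusted over the list alone; median 0.06, adjusted p = 0.663), nor any neutrophil marker of 13 (0 and 0, also adjusted over the list alone; median 0.10, adjusted p = 0.530). Of these markers 9 of 19 and 6 of 13 had a mean signal below the median of the negative controls. Of 8 erythroid markers 1 rose, with means below that median in both groups, and 0 fell, the same adjusted over the list alone (median 0.07, adjusted p = 0.885).

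Sex-linked transcripts separated the groups on every array. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were at least 8.15-fold, 3.35-fold, 3.97-fold and 2.24-fold higher in the infected group, and lay below the negative-control median in the uninfected group. Xist, the noncoding RNA of X inactivation in females, fell by 1.08 ± 0.09, from 9.62 to 8.54, and remained well above the 95th percentile of the negative controls on infected arrays, 6.44. All 5 listed genes passed, 4 higher and 1 lower, also adjusted over the list alone (list median 2.29, adjusted p = 0.0011; adjusted p = 0.333 with an estimated correlation).

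Control probe sets also differed between groups. Hybridisation controls, labelled RNA added to every array at fixed amounts, averaged 10.1 ± 0.25 (SD, n = 3) on infected and 9.15 ± 0.26 (SD, n = 3) on uninfected arrays, and poly-A controls, added to the RNA before labelling, 5.79 ± 0.02 and 6.96 ± 0.25. Both differences have p = 0.1 in two-sided exact permutation tests, the smallest p that 3 against 3 arrays allow. The median of protein-coding genes differed by 0.0078 (exact permutation p = 0.6). Of the 42 lists 25 passed with the preset correlation. The other 9 ways of splitting the 6 arrays into groups of 3 gave between 7 and 19 lists by the same test and 0 changed genes (limma; 552 to 1272 genes at an unadjusted p under 0.05). Each of these mixes infected with uninfected arrays, so the difference between infected and uninfected enters the spread within groups. The lack of gene calls follows largely from that, and the list counts are no clean measure of chance.

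**Figure D3:**
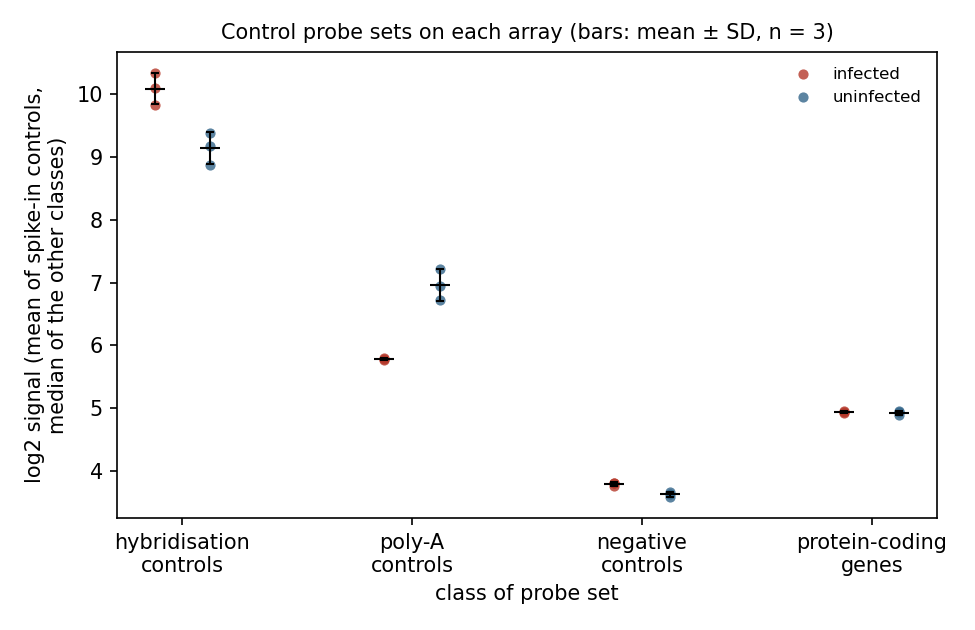
Log2 signal (vertical axis) of control probe sets and protein-coding genes (horizontal axis) on each array, infected in red and uninfected in blue, as means for spike-in controls and medians otherwise, with black bars for mean ± SD (n = 3). Hybridisation controls lie higher by 0.95 and poly-A controls lower by 1.17 on infected arrays.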

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

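The tests in this part were chosen after the result was seen, except the counts over other splits of the arrays. Hybridisation control probe sets, which no comparison between genes uses, were higher by 0.95 (log2) on infected arrays. Among 25795 transcript clusters without a gene symbol, also outside the comparisons, 1697 were higher and 432 lower on infected arrays.

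The changes in gene lists coincide with differences between the groups other than infection. In place of infection, donor sex could account for part of them: 0 arrays have a Y-linked signal that lies with the other group, so donor sex and infection cannot be told apart here. A separate preparation or hybridisation batch for each group is also open, because 2 of 2 kinds of spike-in control split the arrays by group. Time in culture could not be compared either, since no hours are recorded for the uninfected cells. Infection itself stays open as well and was not tested against these. Without sex-linked and sex-biased genes, 23 of the 24 passing lists that could still be tested passed, all but that of bile acids, which bears only on the genes removed.

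The 6 arrays can be split in 10 ways, too few for a share under 0.05. All splits but the real one mix infected with uninfected arrays, so the group difference widens the spread within their groups. Calls of 0 genes in them follow largely from that mixing, and their list counts are no clean measure of chance. The real split was the 1 of 10 with the most calls in each case: 9155 changed genes against at most 0 in the others, 1049 at least 2-fold against at most 0, and 25 lists against at most 19.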

How the results depend on the processing

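Fits on protein-coding genes, on 1 gene per set of identical values and without sex-linked and sex-biased genes were chosen after seeing the data; the other alternatives were planned. No named gene or list that passed changed the sign of its difference or median, whereas 9 lists and 2 named genes that did not pass did so. Of 167 named genes that passed, 157 passed under each alternative run for them, and 17 of these were absent from at least 1 alternative that removes genes. Of 25 lists, 16 passed under each alternative run for them except the estimated correlation, under which 1 list passed. With fry 33 lists passed, 8 of them not called by camera. Counts of changed genes lay between 5989 and 8473 with 1 array left out, at least 2-fold between 1047 and 1091, and lists between 22 and 25. At least 2-fold changes numbered 357 among protein-coding genes, since most others are short RNA genes. With array medians subtracted, 34.0% of changed genes were higher, against 48.4% as deposited. The medians were higher by 0.063 on infected arrays, and subtracting them lowers every difference by that amount. The balance of higher and lower calls thus rests in part on this small offset, whose source was not tested. The cause of the losses with an estimated correlation was not tested. Some estimates lay well above the preset 0.01, such as 0.43 for the proteasome list. Those for DNA replication and sinusoidal endothelial genes, 0.006 and -0.04, lay below it, and these calls were lost too. A higher correlation thus does not account for the loss of those calls. With the replicate number as a block, 7525 genes, 1049 genes at least 2-fold and 22 lists passed, without those of glycolysis, ATF4 and bile acids. Deviations of same-numbered arrays correlated between -0.08 and -0.01, and 0 of 3 infected arrays correlated best with its own number, so the numbers do not pair the arrays. A change of pseudocount was not run because the values are logarithms. Negative controls reach 6.44 at their 95th percentile on infected arrays, so changes among dimmer genes rest on signal within the background range.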

Other observations

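The gene groups and tests in this part were chosen after the result was seen. Short noncoding RNAs made up much of the upper end of the changes. Of 920 snRNA genes in RefSeq 569 rose and 2 fell, and of 976 snoRNA genes 421 rose and 5 fell. Of 62 rRNA genes 60 rose and 1 fell. The rise did not extend to the 45S rRNA and its fragments. Of the 3 genes Rn18s, Rn28s1 and Rn45s, 0 rose and 1 fell, with a median of -0.18. The median snRNA gene lay at 3.70 on infected and 3.17 on uninfected arrays, and the median snoRNA gene at 3.57 and 3.20. These lie below the negative-control medians of 3.80 and 3.63, so much of both classes was measured at background level. Negative controls were themselves higher by 0.16 on infected arrays. Several copies share identical values, and the 62 rRNA genes hold 23 distinct sets. Rmrp and Rpph1, the RNA subunits of RNase MRP and RNase P, rose by 2.15 ± 0.11 and 1.93 ± 0.10. The 7SK RNA gene Rn7sk rose by 0.40 ± 0.06. Of 950 miRNA precursor genes 109 rose and 35 fell.

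Genes with sex-biased expression in mouse liver moved in the direction of male liver. They were listed from general knowledge after the largest changes had been seen. Of 31 female-biased genes 21 fell and 2 rose, Cyp39a1 (0.98) and Lpl (0.80). Of 25 male-biased genes 18 rose and 0 fell, among them Selenbp2 (1.62), Mup20 (1.48) and Cyp2d9 (0.88). Among X-linked genes that escape inactivation, Eif2s3x fell by 0.96 and Ddx3x by 0.55, while Kdm6a at -0.11 and Kdm5c at -0.16 did not pass.

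Y-linked genes were higher and Xist lower on infected arrays. Parasite RNA binding the Y-linked probes stays open, since the fall of Xist, at -1.08, is part of the pattern and says nothing of those probes. Cells from male mice in the infected cultures, mixed with female cells, may account for both: of the sex-biased genes that passed and were not already named or listed, 93.1% moved in the male direction. A lower share of female cells alone was read from Xist, with signal taken as proportional to RNA. As the whole cause of the fall of female-biased genes it is argued against only by genes not already named or listed. Of these 24, 8 lay below Xist by more than 2 standard errors of each. The cut-off was set after the values were seen. Some of the 8, such as Cyp3a44 and Sult2a1, share families with named genes and are not independent. Of all 31 genes 14 lay below Xist, but these include large falls seen before the list was written, so that count is no test. As part of the cause a lower share of female cells stays open.

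The rise of short noncoding RNAs has several candidate explanations. Parasite RNA binding conserved probes, as the whole cause, was weighed for the 83 named snoRNA and scaRNA genes, of which 74.7% rose. Their sequences differ more between distant species than that of 5S rRNA. The share that rose is part of the pattern, however, and its cut-offs were set after it was seen, so it cannot decide. Of all 976 RefSeq snoRNA genes 43.1% rose, which leaves that class undecided too. No probe sequence was compared with parasite RNA. For 5S rRNA, binding of parasite RNA cannot be told apart from preparation. Distinct RefSeq rRNA genes exceed the named snoRNA and scaRNA genes by 1.52 in median. By contrast, 5S genes taken by name had a median of 0.54 against 0.70 over distinct sets of values. Over all genes it was 0.79 against 0.68. More short RNA carried into labelling may also contribute. A median at or below 0 in an abundant class was set to count against it. As run, however, the test could return only a fit or no decision. The lowest of 8 class medians was -0.62, for the single gene Rn4.5s (limma, adjusted p = 0.021). That value met the condition. It rests on 1 gene, whose likeness to B1 repeats in mRNA leaves it undecided, so no conclusion is drawn for or against. The 8 classes leave out miRNA precursors, of which 11.5% rose (median 0.11). A response of the host cell to infection was not tested and stays open.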
